A study of Mus musculus with 8 samples.

How the data were processed

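RNA of primary mouse microglia, the resident macrophages of the brain, was measured on 8 one-colour Agilent arrays, 2 for each of 4 treatments. The cells were exposed for 3 h to PBS, to 20 µg/ml of an antibody Fc fragment, or to 20 µg/ml of Fc fused to residues 71 to 132 or to residues 133 to 148 of Ecrg4. The labels number the arrays of each treatment 1 and 2 and call these numbers sets, which are written here as set 1 and set 2. Nothing says that the sets came from separate cultures or animals, so the p-values of single genes measure only the spread between these samples.

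The deposited scanner files hold background-subtracted spot intensities on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes. The deposited table of processed values holds log2 values, and these follow log2 of the scanner intensity minus 1 constant per array, with a correlation of 1 across probes in each of the 8 columns. That table is not centred by gene, and its column medians ran from -4.49 to -4.21. The step by which the authors chose the constant is not given in the sources used here. The files also hold flags for spots that are saturated, outlying or not well above background. No spot was saturated.

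From these files, log2 intensity minus the 75th percentile of each array's non-control spots was computed, spots of 1 probe were averaged, and outlying spots were left out. Of 55681 probes, 28026 were named through RefSeq accessions, without versions, in a gene table of the assembly GRCm38.p6, and 27655 kept the name in the files. The array was designed on another build, so no coordinates are given. Probes well above background on both arrays of at least 1 group were kept (25287), and the brightest probe stood for each gene, which left 19117 genes, 12595 of them with a symbol. For 4467 genes 1 of several kept probes was used, and the mean of the probes was an alternative. Another 104 probes were left out because each of their spots was outlying on some array. Limma 3.58.1 in R 4.3.3 was fitted to all 8 arrays with 1 mean per group and 4 residual degrees of freedom. Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. A gene with 1 group not well above background on any array has only a bound, written "at least": the mean of the brighter group against the mean, per array of the dim group, of the higher of the lowest signal among probes well above background and the dim probe's own. Values are log2 signals, with the array's 75th percentile at 0, unless stated otherwise. Means and medians of lists use no such bounds and take each gene's signal as measured, also where it was not well above background. The number of arrays limits the precision of every value.

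The comparisons, the tests, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists were tested with camera in limma, with a preset correlation of 0.01 between genes, where at least 5 members were measured, which held for 23 lists. Camera compares the genes of a list with all other genes. Its p-values at the preset correlation therefore depend on genes varying almost independently, and do not measure the spread between samples alone. Camera with an estimated correlation and fry were run beside it. The rule names, where no gene passes, the 3 genes with the smallest unadjusted p in each direction, then the brightest member of each list, and a set of receptors and cytokines. The text leaves some of these out. Genes outside the rule are said to have been chosen after their values were seen.

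Whether the set numbers pair the samples was checked by a rule of a fixed correlation, although the number of genes called with the set as a block had by then been seen. The differences between set 1 and set 2 correlated at 0.78 to 0.86 across genes in the 6 pairs of groups, and the sets lay in separate columns of 1 slide. The sets were therefore taken as pairs and as a batch in the fits with a block and in the folds within each set. The main fit, fixed before the data were examined, leaves the set out. All arrays were on 1 slide, and no slide effect could be fitted. Fold changes within each set are given for some genes and lists, and fits with the set as a block where stated. Every SE, and every test not said to use the block, is from the fit without it. The spread in that fit includes the difference between the sets. Alternatives covered normexp background correction (offset 50, on the median spot signal because the files used here hold no mean signal), quantile and median scaling, filters, probe rules, moderation, thresholds, the deposited log2 table, and each array left out in turn. The closing section gives their effect.

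The gene test was run on simulated arrays of Ecrg4(71-132) against Fc with the measured set differences, 19117 genes and known changes. Without the block it recovered 0 of 67 genes changed by 1 on the log2 scale, 27 of 67 changed by 2 and 50 of 66 changed by 4. With the block it recovered 49 of 67, 62 of 67 and 65 of 66, with 6 false calls. In the simulation each gene's change was equal in both sets.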

Results

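The study asked how mouse microglia respond to 2 fragments of Ecrg4, a secreted precursor protein, each fused to an antibody Fc fragment. Gene expression was measured after 3 h of treatment with PBS, Fc, Ecrg4(71-132) or Ecrg4(133-148), with 2 arrays in each of the 4 groups. Between 24254 and 29483 probes per array were well above background. The 75th percentile of signal ran from 494.7 to 809.4. Arrays resembled others of their set more than their own duplicates: the correlation across genes was 0.994 to 0.997 within set 1, 0.975 to 0.990 within set 2 and 0.954 to 0.962 between the duplicates of a group. The first principal component separated the sets and held 71.6% of the variance, and the next held 14.2%. Values within each set are therefore given beside the mean of both for some genes and lists, and the other values are means over both sets.

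Ecrg4(71-132) was compared with Fc, the carrier control at the same dose. Of the cytokine, chemokine and NF-kB pathway genes, 15 of 18, 13 of 20 and 28 of 29 were higher in both sets, and the median folds of the 3 lists were larger in set 2. Il1b, which encodes the cytokine interleukin-1 beta, was 4.48 higher on the log2 scale (SE 1.31), by 3.01 in set 1 and 5.95 in set 2. Tnf, another inflammatory cytokine gene, was 2.94 higher (SE 0.77), by 1.75 and 4.14. Il6 was 3.97 higher (SE 1.70), by 2.03 and 5.91. Nos2, the inducible nitric oxide synthase gene, was 0.98 higher (SE 0.32), by 0.91 and 1.04. None of these passed the test over all genes (limma, adjusted p = 1). The SEs include the difference between the sets.

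In all, 8 lists shifted upward with Ecrg4(71-132), and none downward. The 18 measured pro-inflammatory cytokine and colony-stimulating factor genes had a mean fold of 2.30 on the log2 scale (camera in limma, adjusted p = 8.24e-12), and 15 were higher in both sets. The size of this mean is uncertain, as some members were not well above background. With Fc in set 2, Csf2 stood at -5.82 and Csf3 at -5.69, where the lowest signal well above background was -3.72. The chemokine list also held such members. The 29 NF-kB pathway genes averaged 1.27 (adjusted p = 1.22e-20), with 28 higher in both sets. The 20 chemokine genes averaged 1.28 (adjusted p = 1.59e-06), with 13 higher in both sets, and the 27 interferon-stimulated genes averaged 0.70 (adjusted p = 0.00294), with 26 higher in both sets. The interferon count depends on the Fc arrays, whose median for this list lay above PBS in set 1 and below it in set 2. In set 2 some members, such as Usp18 and Oasl2, were lower with Ecrg4(71-132) than with PBS, and others, such as Isg15 and Gbp5, were higher. These examples were chosen after their values were seen. Matrix protease genes averaged 0.69 (adjusted p = 7.68e-05), immediate-early genes 0.41 (adjusted p = 0.000269), oxidative stress genes 0.33 (adjusted p = 0.00123) and glycolysis and hypoxia genes 0.37 (adjusted p = 0.00407). No call held with an estimated correlation, where these lists had adjusted p from 0.135 to 0.761. Over all genes no list member passed, and adjusted over the list alone 1 did, Serpinb2 among the matrix protease genes. Adjusted over the list alone with the set as a block, 32 members of the tested lists passed, among them 15 of the 18 cytokine genes, 4 matrix protease genes and 2 chemokines. The median fold in set 1 and set 2 was 1.37 and 3.26 for the cytokine genes, 0.75 and 1.06 for the chemokines, 0.48 and 1.75 for the NF-kB genes, and 0.43 and 0.47 for the interferon-stimulated genes. Leaving out 1 array compares means over different sets, so each array was also left out with the set as a block, an alternative added after the data were seen. All 8 calls then held without any 1 array, except that of the oxidative stress genes without the first Ecrg4(71-132) array (adjusted p = 0.0557). The lowest mean in these fits was 0.30 for the interferon-stimulated genes and 1.57 for the cytokine genes.

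**Figure D1:**
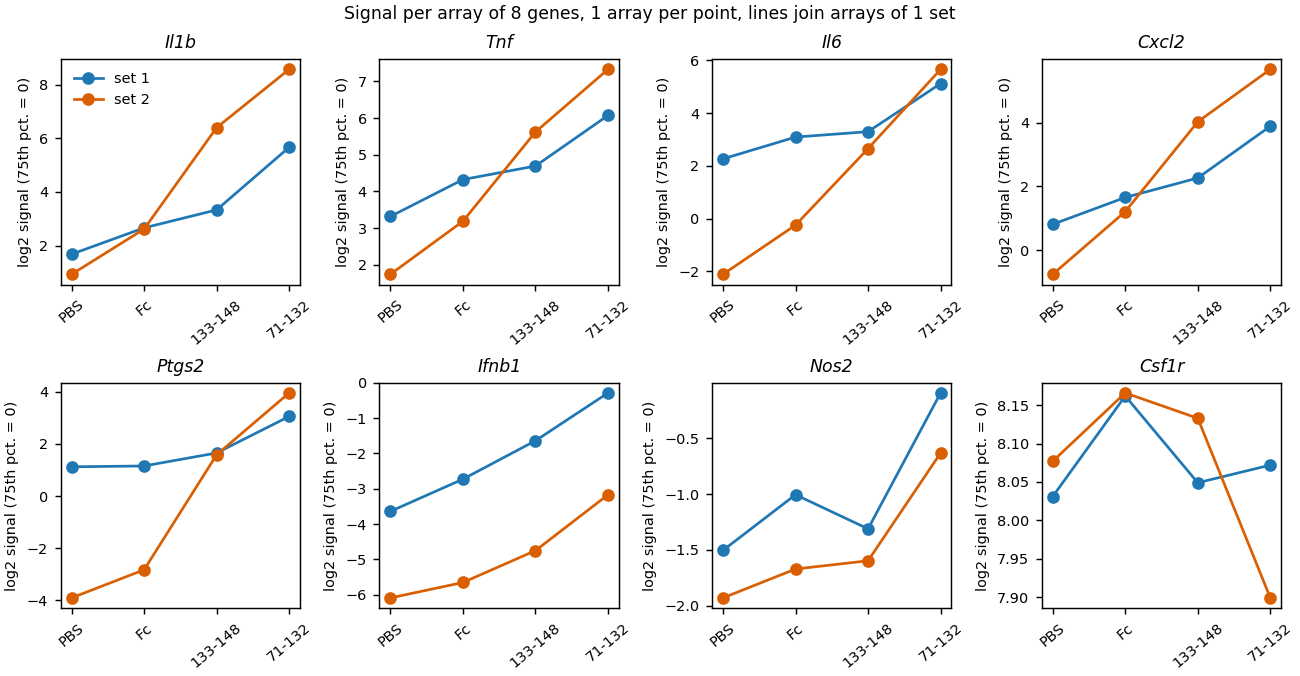
Log2 signal (array 75th percentile = 0) of 8 genes on each of the 8 arrays, by treatment, with points of 1 set joined by a line. Il1b was 3.01 higher with Ecrg4(71-132) than with Fc in set 1 and 5.95 higher in set 2; Cxcl2, Ptgs2 and Ifnb1 were chosen after their values were seen.

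By the rule for genes when none passed, Serpinb2, a serine protease inhibitor gene, was 2.92 higher (SE 0.37, 2.27 and 3.58 within the sets), Cgref1 was 1.21 higher (SE 0.22) and Smim3 0.96 higher (SE 0.17). Armc2 was lower, at -1.67 (SE 0.21), as were Cbfa2t3, a transcriptional corepressor gene, at -1.22 (SE 0.17) and Frat1 at -0.96 (SE 0.15). None passed the test.

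In all, 88 genes were over 2-fold higher and 51 over 2-fold lower within both sets, against 6.27 and 6.84 for independent sets, and 5 went opposite ways by as much. The numbers for independent sets, here and below, take every gene as equally variable. They are too low where some genes vary more than others in both sets. With normexp background correction 55 were higher and 3 lower, and 14 were lower among genes well above background on all 8 arrays. This count was added after no gene passed the test. Among the genes chosen from it after their values were seen, Il1a was 3.35 higher, Cxcl2 3.34, Cxcl3 3.56, Ptgs2 4.34, Nfkbiz 1.88, Socs3 1.72, Slc7a11 1.62 and Col5a3 4.14. These means can hide wide differences between the sets. Ptgs2 stood at 1.15 with Fc and 3.05 with Ecrg4(71-132) in set 1, and at -2.83 and 3.95 in set 2. Il1a stood at 0.73 and 3.18 in set 1, and at 1.19 and 5.43 in set 2. Csf2 (4.71), Csf3 (3.38), Ereg (5.19) and Ifnb1 (2.46) were also higher, each well above background on 1 of 2 Fc arrays. Gpr34, a microglial receptor gene, was at -1.26, Bmf at -1.57 and Rnf144b at -1.73.

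No gene passed in this comparison in limma, while 643 had an unadjusted p under 0.05, against 956 by chance. That fit leaves the difference between the sets in its spread, so a count below 956 is no sign of a lack of change. With the set as a block none passed either, and 3558 had an unadjusted p under 0.05.

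Ecrg4(133-148) was compared with Fc in the same way. Of the cytokine, chemokine and NF-kB pathway genes, 13 of 18, 10 of 20 and 16 of 29 were higher in both sets, and the median folds of the 3 lists were larger in set 2. Il1b was 2.23 higher (SE 1.31), by 0.67 in set 1 and 3.78 in set 2. Tnf was 1.40 higher (SE 0.77), by 0.37 and 2.43, and Il6 was 1.55 higher (SE 1.70), by 0.21 and 2.90. Serpinb2 was 2.11 higher (SE 0.37), by 1.59 and 2.64. None passed the test (limma, adjusted p = 1).

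With camera, 7 lists shifted upward with Ecrg4(133-148). The NF-kB genes averaged 0.52 (camera, adjusted p = 1.23e-07), the cytokine genes 0.89 (adjusted p = 0.000101), the chemokines 0.47 (adjusted p = 0.00106), the immediate-early genes 0.25 (adjusted p = 0.00106), the matrix protease genes 0.38 (adjusted p = 0.00106), the oxidative stress genes 0.17 (adjusted p = 0.00665) and the glycolysis and hypoxia genes 0.20 (adjusted p = 0.019). With an estimated correlation the adjusted p ran from 0.262 to 0.455 and none was called. In set 1 the median fold was 0.07 for the cytokine genes, 0.02 for the NF-kB genes and 0.13 for the chemokines, against 1.45, 0.84 and 0.77 in set 2. Immediate-early genes had medians of 0.20 and 0.21. Among fits with the set as a block, 3 of the 7 calls held without the second Fc array and 2, the immediate-early and matrix protease genes, without the second Ecrg4(133-148) array. The cytokine genes then averaged 0.34 (adjusted p = 0.586) and 0.44 (adjusted p = 0.701). All 7 held without any other array. Interferon-stimulated genes had a median of -0.50 in set 1 and 0.24 in set 2 and were not called (adjusted p = 0.91). Serpinb2 alone passed when adjusted over the list alone, and 2 members did with the set as a block, 1 of them a chemokine.

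Of the remaining genes the rule names, Cass4 was 1.26 higher (SE 0.23, well above background on 1 of 2 Fc arrays) and Gramd1b 0.67 higher (SE 0.19). Dpf1 was at -0.93 (SE 0.22), Slc7a3, an amino acid transporter gene, at -0.68 (SE 0.17) and Brd8 at -0.57 (SE 0.15). In both sets 10 genes were over 2-fold higher and 5 over 2-fold lower, against 1.82 and 1.42 for independent sets, and 7 went opposite ways. As those numbers take every gene as equally variable, the counts do not show that the changes repeat. With normexp these counts were 1 and 0. Chosen from these after their values were seen, Fosl1 was 1.11 higher and Bcl6b 1.65 higher. Atp12a was at least 1.36-fold higher, with Fc not well above background, and Ano1 at least 1.61-fold lower, with the fragment not well above background. No gene passed in limma, with 88 at an unadjusted p under 0.05 without the block and 1006 with it.

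**Figure D2:**
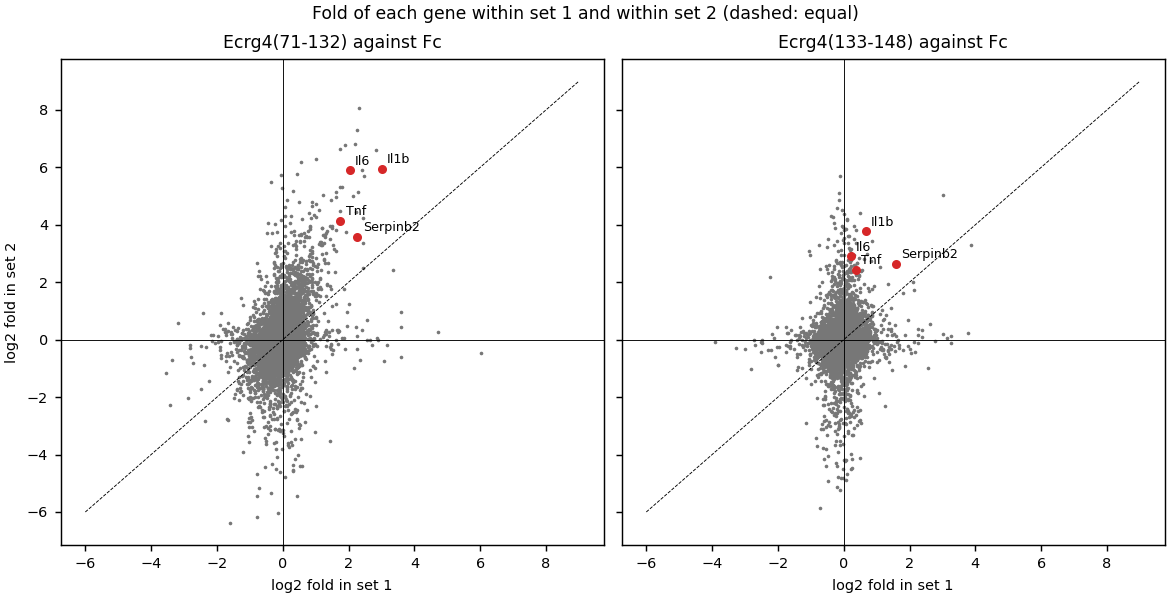
Log2 fold against Fc of each of the 19117 genes within set 1 (horizontal) and within set 2 (vertical), for both fragments, with equal folds on the dashed line. The correlation across genes was 0.403 for Ecrg4(71-132) and 0.135 for Ecrg4(133-148), where genes are not independent replicates.

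The fragments were then compared directly. The difference, Ecrg4(133-148) minus Ecrg4(71-132), was -2.25 for Il1b (95% interval -5.56 to 1.05), -1.54 for Tnf (-3.48 to 0.39), -2.41 for Il6 (-6.70 to 1.87) and -1.09 for Nos2 (-1.91 to -0.28). Within set 1 and set 2 the differences were -2.33 and -2.17 for Il1b, and -1.38 and -1.71 for Tnf. None passed the test (limma, adjusted p = 1). These intervals carry the set difference. With the set as a block they were -5.24 to 0.73 for Il1b, -3.71 to 0.62 for Tnf, -5.87 to 1.04 for Il6 and -1.38 to -0.81 for Nos2 (adjusted p = 0.714 for each). The intervals are not adjusted for the number of genes, and all but those of Nos2 include 0.

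Between the fragments, 8 lists were lower with Ecrg4(133-148). The mean difference was -1.42 for the cytokine genes (camera, adjusted p = 4.83e-11, 17 of 18 lower in both sets), -0.75 for the NF-kB genes (adjusted p = 6.59e-17, 28 of 29), -0.81 for the chemokines (adjusted p = 7.24e-05, 12 of 20) and -0.75 for the interferon-stimulated genes (adjusted p = 6.1e-06, 25 of 27). It was -0.31 for matrix protease genes (adjusted p = 0.0101), -0.25 for antigen presentation genes (adjusted p = 0.0405), -0.15 for oxidative stress genes (adjusted p = 0.0405) and -0.16 for immediate-early genes (adjusted p = 0.0423). With an estimated correlation their adjusted p ran from 0.23 to 0.564. With the set as a block the oxidative stress genes were no longer called (adjusted p = 0.0906), while anti-inflammatory genes (mean -0.29, adjusted p = 0.0169) and glycolysis and hypoxia genes (mean -0.17, adjusted p = 0.0471) were called lower and cell cycle genes (mean 0.10, adjusted p = 0.00556) higher. These 3 were lost with the block and an estimated correlation, with adjusted p = 0.361, 0.369 and 0.56 in that order. Adjusted over the list alone, 0 list members passed without the block and 2 with it, an NF-kB gene and an interferon-stimulated gene. Each array was also left out with the block. The cytokine and interferon-stimulated genes then held without any 1 array, with means of -2.15 to -0.69 and -0.91 to -0.58. The chemokines lost their call without the first Ecrg4(133-148) array (adjusted p = 0.129), and the NF-kB (adjusted p = 0.0832) and matrix protease genes (adjusted p = 0.0995) without the second Ecrg4(71-132) array. The immediate-early and antigen presentation genes lost theirs without either of these arrays or the first Ecrg4(71-132) array.

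By the rule, Armc2 (1.05, SE 0.21), Klf8 (0.63, SE 0.14) and Cbfa2t3 (0.69, SE 0.17) were higher with Ecrg4(133-148), and Fndc7 was lower (-1.53, SE 0.41). Grm4 was at least 1.74-fold and Sprr2e at least 1.4-fold higher with Ecrg4(71-132), with Ecrg4(133-148) not well above background. In both sets 78 genes were over 2-fold lower and 26 over 2-fold higher with Ecrg4(133-148), against 5.28 and 3.54 for independent sets. With normexp they numbered 44 and 2. Another 8 went opposite ways. Chosen after their values were seen, Ccl5 was at -2.60, Csf2 at -2.76 (1 of 2 Ecrg4(133-148) arrays well above background), Il1a at -1.85 and Rgs2 at 1.22. Ifit1, Rsad2 and Cxcl10, interferon-responsive genes, were at -1.34, -1.26 and -1.61, with set differences of -1.34 and -1.34, -1.26 and -1.25, and -1.46 and -1.75. No gene passed in limma, with 141 at an unadjusted p under 0.05 without the block and 1210 with it.

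Fc was compared with PBS to measure the effect of the carrier. The 29 NF-kB genes averaged 0.41 higher (camera, adjusted p = 1.48e-10), 28 of them in both sets, with medians of 0.30 and 0.52. This call did not hold with an estimated correlation (adjusted p = 0.725). With the set as a block it was also lost without the first Fc array (mean 0.07, adjusted p = 0.831) and without the second PBS array (mean -0.14, adjusted p = 0.142). Tnf was 1.23 higher (SE 0.77, 1.01 and 1.45 within the sets), Il1b 1.34 (SE 1.31) and Il6 1.35 (SE 1.70). Interferon-stimulated genes had medians of 0.77 in set 1 and -0.27 in set 2 and were not called (adjusted p = 0.498). With the set as a block, 3 lists were called: the NF-kB genes (adjusted p = 0.00025), the interferon-stimulated genes (adjusted p = 0.0494) and the astrocyte markers (adjusted p = 4.9e-05), the last lower, with medians of -1.01 in set 1 and -0.0012 in set 2. None of the 3 held with the block and an estimated correlation (adjusted p = 0.765 for each). By the rule, Dpf1 (0.80, SE 0.22), Mfsd6l (0.75, SE 0.25) and Nav3 (0.67, SE 0.24, well above background on 1 of 2 Fc arrays) were higher. Tfr2 was at least 1.6-fold, Hs3st1 at least 1.23-fold and Npy1r at least 2.67-fold higher in PBS, with Fc not well above background. In both sets 8 genes were over 2-fold higher and 23 over 2-fold lower with Fc, against 1.17 and 1.9 for independent sets, and 18 went opposite ways. With normexp 1 was higher and 1 lower. Over genes well above background on all 8 arrays 3 were higher and 1 lower. Chosen after its values were seen, Acod1 was 1.31 higher (SE 2.08). No gene passed in limma, with 51 at an unadjusted p under 0.05 without the block and 355 with it.

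Against PBS, Il1b was 5.82 higher with Ecrg4(71-132) and 3.56 higher with Ecrg4(133-148), and Tnf 4.17 and 2.63 higher. No gene passed for either fragment in limma, with 932 and 186 genes at an unadjusted p under 0.05, and 4530 and 1748 with the set as a block. In both sets 137 genes were over 2-fold higher and 85 lower with Ecrg4(71-132), with 15 opposite, and 25 were higher and 41 lower with Ecrg4(133-148), with 44 opposite. With normexp 11 were lower with Ecrg4(71-132). For Ecrg4(133-148) normexp gave 12 higher and 2 lower, so the balance of directions turned. Camera called 8 lists for Ecrg4(71-132) and 6 for Ecrg4(133-148), and none with an estimated correlation, where the called lists had adjusted p from 0.126 to 0.776 and of 0.239. Over the list alone, 9 list members passed for Ecrg4(71-132) against PBS, among them Tnf, Il1a and Il1b. In the fit with the set as a block 88 did, 25 of them NF-kB genes and 14 cytokine genes, and for Ecrg4(133-148) against PBS 5 did, against 1 without it. In set 1, 35 of the 67 cytokine, chemokine and NF-kB genes were ordered PBS, Fc, Ecrg4(133-148), Ecrg4(71-132) from low to high, and in set 2 it was 46, against 2.79 for a random order. The 2.79 takes the genes as independent, but they move together and each set holds 1 array per group. It is therefore no test of the order, which was not among the results fixed before the data were examined.

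No gene was called for both fragments against Fc. Over 2-fold in both sets, 5 genes were higher and 1 lower with both. The folds of the fragments against Fc correlated at 0.635 across genes, and at 0.499 on average in 100 simulations of unchanged groups against shared Fc arrays. The covariance was 0.0807, against 0.0286 in the simulation, a difference of 0.0522. With Ecrg4(133-148) of set 1 against Ecrg4(71-132) of set 2, which share no array, the correlation was 0.141, and it was 0.28 with the sets exchanged. The covariance in these 2 cases was 0.0257 and 0.0454. With Ecrg4(133-148) against Fc and Ecrg4(71-132) against PBS, which share no array, it was 0.0583 (correlation 0.411). With the controls exchanged it was 0.0668 (correlation 0.456). A covariance thus remained without a shared control array. The 2 Fc arrays could not be split with 2 in each part, so part of the excess may come from the shared controls.

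**Figure D3:**
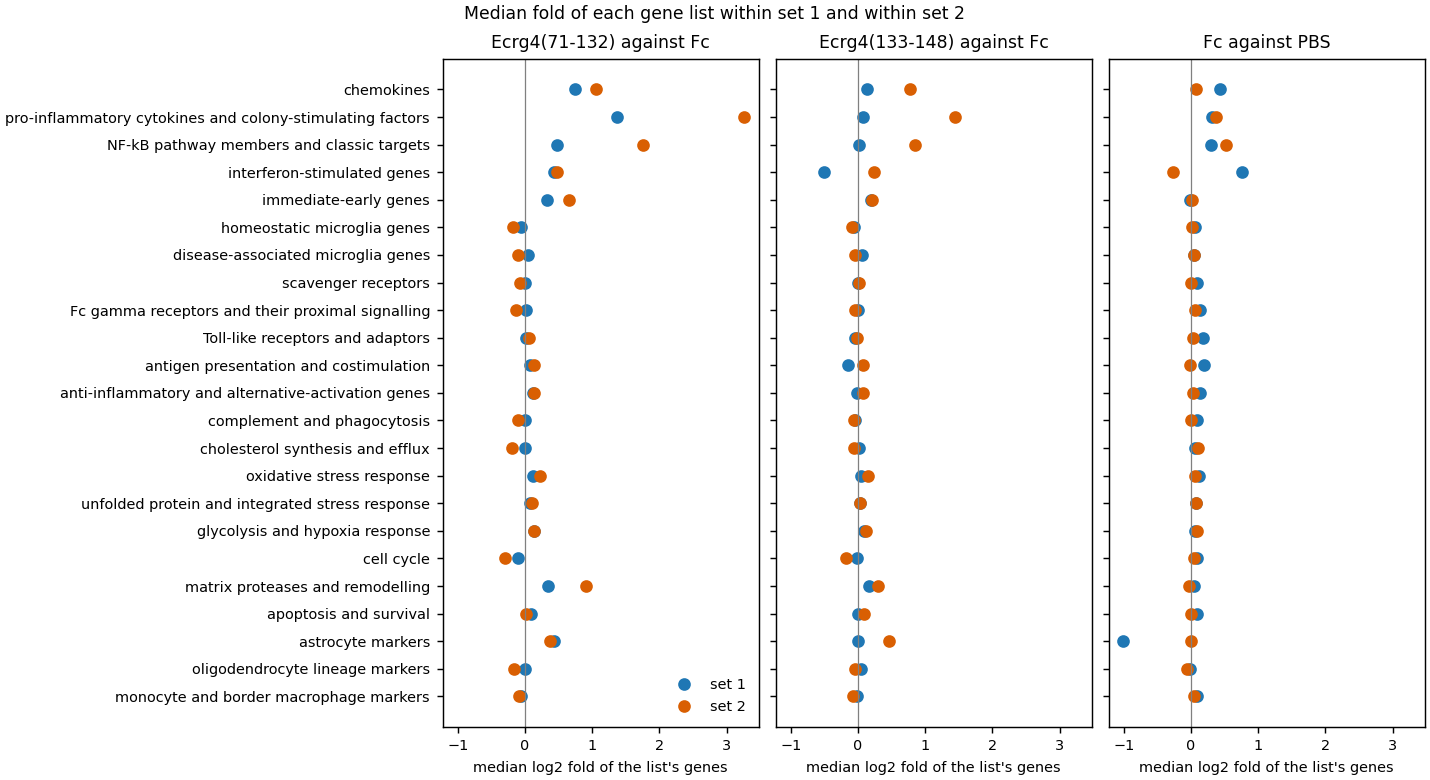
Median log2 fold of the members of the 23 lists tested, within set 1 and within set 2, for both fragments against Fc and for Fc against PBS. Cytokine genes stood at 1.37 in set 1 and 3.26 in set 2 with Ecrg4(71-132), and at 0.07 and 1.45 with Ecrg4(133-148).

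Neither receptor list passed the test. With Ecrg4(71-132), the 15 genes of Fc gamma receptors and their signalling had a median of -0.10 (camera, adjusted p = 0.433) and the 15 scavenger receptor genes -0.06 (adjusted p = 0.925). Fcgr2b was at 0.15 (SE 0.40), Fcgr3 at -0.18 (SE 0.15), Fcgr4 at -0.24 (SE 0.58), Fcgr1 at -0.76 (SE 0.99), Cd36 at 0.20 (SE 1.09) and Msr1 at 0.24 (SE 0.13). Olr1, an oxidised lipoprotein receptor gene, was 1.43 higher (SE 1.70), by 1.09 and 1.78 within the sets. These SEs include the difference between the sets. Ecrg4 itself was well above background on 4 of 8 arrays, never on both of a group, and was not tested; Scarf1 was so on 1 array. Of the other lists, homeostatic microglia genes had a median of -0.10 with Ecrg4(71-132) (adjusted p = 0.532), disease-associated microglia genes -0.02 (adjusted p = 0.767), Toll-like receptor genes 0.02 (adjusted p = 0.499), anti-inflammatory genes 0.16 (adjusted p = 0.064), complement genes -0.03 (adjusted p = 0.804), cholesterol genes -0.04 (adjusted p = 0.767), unfolded protein response genes 0.05 (adjusted p = 0.319), cell cycle genes -0.23 (adjusted p = 0.767) and apoptosis genes 0.04 (adjusted p = 0.188). Antigen presentation genes had a median of 0.13 (adjusted p = 0.285), and with the set as a block they were called higher (adjusted p = 0.0499), as were anti-inflammatory genes (adjusted p = 0.033), while cell cycle genes were called lower (adjusted p = 0.00134). These calls were lost with the block and an estimated correlation, with adjusted p = 0.525, 0.314 and 0.525 in that order.

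Markers of other cell types were measured in part. With Ecrg4(71-132) against Fc the 8 astrocyte markers had a median of 0.31 (adjusted p = 0.515), the 8 oligodendrocyte lineage markers -0.0012 (adjusted p = 0.925) and the 6 monocyte and border macrophage markers -0.07 (adjusted p = 0.804). The neuron (2 measured), endothelial (3), fibroblast (4), neutrophil (3) and lymphocyte (3) markers were too few to test, with medians of -0.13, 0.00102, 0.06, 0.26 and -0.21. Within set 1 and set 2 the fibroblast median was 0.04 and 0.08 with Ecrg4(71-132) against Fc, -0.46 and 0.56 with Ecrg4(133-148) against Fc, -0.51 and 0.35 between the fragments, and -0.60 and -0.02 for Fc against PBS. Against PBS it was -1.05 and 0.44 with Ecrg4(133-148) and -0.61 and -0.09 with Ecrg4(71-132). The astrocyte medians were 0.44 and 0.37 with Ecrg4(71-132) against Fc, with 4 of 8 markers higher in both sets and 0 lower, and -0.44 and -0.20 between the fragments, with 4 lower in both sets and 0 higher. They were 0.00409 and 0.45 with Ecrg4(133-148) against Fc. Neither of the first 2 was called, with or without the block. Against PBS they were -0.98 and 0.45 with Ecrg4(133-148) and -0.51 and 0.09 with Ecrg4(71-132). Between the sets, 6 of the 8 astrocyte markers and 4 of the 4 fibroblast markers were over 2-fold higher in set 1, with median log2 differences of 3.2 and 6.32, though several were near the background in set 2. The other 2 astrocyte markers, Aldoc and Aldh1l1, were over 2-fold higher in set 2.

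**Figure D4:**
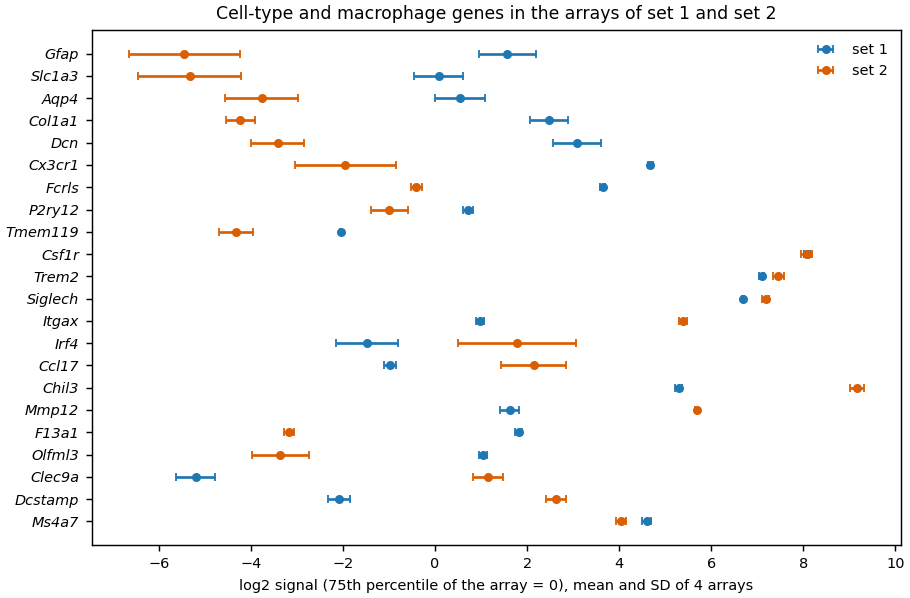
Log2 signal (array 75th percentile = 0) of 22 cell-type and macrophage genes, mean and SD of the 4 arrays of each set, chosen after their values were seen. Gfap averaged 1.57 in set 1 and -5.45 in set 2, where it was well above background on 1 of 4 arrays, and Csf1r 8.08 and 8.07.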

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

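The lists below were singled out because the direct comparison of the fragments, the test of the difference itself, passed the threshold for them (camera). The tests of explanations in this part were all chosen after the values were seen, except the test of array scaling.

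Between Ecrg4(133-148) and Ecrg4(71-132) the mean log2 difference was -1.42 for cytokine genes, -0.809 for chemokines, -0.749 for NF-kB genes, -0.746 for interferon-stimulated genes, -0.312 for matrix protease genes, -0.253 for antigen presentation genes, -0.16 for immediate-early genes and -0.154 for oxidative stress genes. With an estimated correlation none was called, and with the set as a block the oxidative stress genes were no longer called.

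Of the 67 inflammatory genes, 35 in set 1 and 46 in set 2 ordered as PBS, Fc, Ecrg4(133-148) and Ecrg4(71-132). In set 1, 57 of the 67 genes were highest with Ecrg4(71-132), and their median fold against Fc was 0.5454. Set 2 was thus not alone in showing higher values with this fragment. With Ecrg4(133-148) the set 1 median was 0.05508, and whether set 2 alone carries its place in the order stays open. The percentiles of these medians among 10000 random lists of matched level were 100 and 96.84. They cannot decide whether the set 1 values come from the treatments, because set 1 holds 1 array per group and the genes move together. If the Fc part of the proteins acted alone, Ecrg4(71-132) would give the same level as Fc, the comparator at the same dose. The lowest within-set median of the 3 lists was 0.476, for the NF-kB genes in set 1. This value cannot decide the question, because it too rests on 1 array per group and genes that move together. The list calls were also lost with an estimated correlation. A bacterial contaminant of the protein preparations cannot be told apart from an effect of the fragments, which stays open: the lower within-set median of the interferon-stimulated genes was 0.428, as either predicts, and no treatment in the design separates them.

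Between the sets, 449 genes were over 4-fold higher in set 1 and 336 in set 2. Array scaling is argued against, as 95.41% of these genes stayed over 4-fold after quantile normalization. So is the hybridization or scan for differences over 4-fold, as none of the 8 spike-in probes measured on all arrays differed by more than 0.722. All 8 were lower in set 1, by 0.384 to 0.722, so differences of that size between the sets are not covered. Astrocytes and fibroblasts in set 1 may account for the glial and matrix genes, where 83.33% of 12 markers were over 2-fold higher in set 1 (Gfap 1.57 and Col1a1 2.48 there). However, 2 of the 8 astrocyte markers were over 2-fold higher in set 2. Dilution by such cells would lower microglia genes such as Cx3cr1 and Fcrls. Both were higher in set 1, the lower of the log2 differences being 4.043. They were chosen after their values were seen, so they cannot test dilution. The 21 homeostatic microglia genes had a median difference of 0.117, with 7 over 2-fold higher in set 1 and 4 in set 2. Other effects of such cells on Cx3cr1 and Fcrls were not tested. No group in the design differs between the sets, so none of its treatments was tested as a cause.

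The folds of the 67 inflammatory genes with Ecrg4(71-132) against Fc were larger in set 2, with a slope of 2.96. Signals near the background do not explain it: over the 59 genes well above background on all arrays the slope was 2.824. Nor does a higher starting level in set 1, since the 35 genes with Fc levels within 1 log2 unit between the sets still had a median excess of 1.092 in set 2. Over all 19117 genes the folds were also wider in set 2, with SDs of 0.334 in set 1 and 0.677 in set 2. For Fc against PBS these SDs were 0.255 and 0.461. A larger response of the 67 genes was thus not separated from a general widening of folds in set 2. Each set holds 1 array per group, and why the sets differ stays open.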

How the results depend on the processing

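The alternatives beyond those planned, among them every count over 2-fold in both sets and each combination of the block with another change, were chosen after seeing the data. No gene passed in any comparison in any planned setting. The replicate block alone called 0 genes in each comparison. In limma, quantile normalization with the block called 1 gene for Ecrg4(71-132) against Fc, 1 for the direct comparison and 1 for Ecrg4(71-132) against PBS. With the block, an intensity trend and a robust prior, Ecrg4(71-132) against PBS gave 74 genes, 37 of them higher, over genes well above background on all 8 arrays, and 2131 with median scaling, 2022 of them higher, where the median of all genes was 0.155 under that scaling. Median scaling moved this median by 0.145, and it moved that of Fc against PBS by 0.0845 and that of Ecrg4(133-148) against PBS by 0.127. With the block and 1 array left out, 0 to 481 genes passed for Ecrg4(71-132) against Fc and 0 to 1077 for Ecrg4(71-132) against PBS. The 481 (296 higher) and 1077 (651 higher) came without the first Ecrg4(71-132) array, so from 1 array of that group, in the set with the larger responses. The others were 1 for Ecrg4(71-132) against Fc without the first Fc array and 3 for Ecrg4(71-132) against PBS without the first PBS array. The cause of these differences was not tested.

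Lists called fell to 0 in the 4 comparisons with an estimated correlation. With fry they fell to 0, except 1 for Ecrg4(71-132) against Fc. Fry with the block called 4 lists for Ecrg4(71-132) against Fc, the chemokines (adjusted p = 0.0415), immediate-early (adjusted p = 0.00467), glycolysis and hypoxia (adjusted p = 0.002) and matrix protease genes (adjusted p = 0.0285), and 0 in the other 3 comparisons. For Ecrg4(71-132) against PBS fry called 1 list without the block and 6 with it, and for Ecrg4(133-148) against PBS 0 and 1. The replicate block called 3 lists and normexp 2 for Fc against PBS, against 1; as a pairing of the sets the block kept all called lists of the fragments against Fc and 7 of 8 of the direct comparison. Leaving out 1 array gave 2 to 9 lists for Ecrg4(133-148) against Fc (2 without the second Fc array, 4 without its own first), 3 to 9 for the direct comparison (3 without the first Ecrg4(71-132) array, 5 without the second Ecrg4(133-148) array) and 1 to 8 for Fc against PBS (8 without the second Fc array, 7 without the first PBS array, 3 without the first Fc array, 2 without the second PBS array). For Ecrg4(71-132) against Fc it gave 6 to 9. With the block it gave 2 to 9 for Ecrg4(133-148) against Fc (4 without the second Fc array, 2 without its own second), 8 to 11 for Ecrg4(71-132) against Fc, 3 to 12 for the direct comparison (5 without the first Ecrg4(133-148) array, 3 without the second Ecrg4(71-132) array) and 2 to 8 for Fc against PBS. The lone array left in a group was assumed to vary like the other groups.

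With normexp, genes over 2-fold in both sets numbered 1 higher for Ecrg4(133-148) against Fc, 0 lower for Ecrg4(133-148) against Fc, 55 higher for Ecrg4(71-132) against Fc, 3 lower for Ecrg4(71-132) against Fc, 2 higher for Ecrg4(133-148) against Ecrg4(71-132), 44 lower for Ecrg4(133-148) against Ecrg4(71-132), 1 higher for Fc against PBS, 1 lower for Fc against PBS, 12 higher for Ecrg4(133-148) against PBS, 2 lower for Ecrg4(133-148) against PBS, 11 lower for Ecrg4(71-132) against PBS. With no filter, genes over 2-fold in both sets numbered 45 higher for Ecrg4(133-148) against Fc, 43 lower for Ecrg4(133-148) against Fc, 113 lower for Ecrg4(71-132) against Fc, 64 higher for Ecrg4(133-148) against Ecrg4(71-132), 128 lower for Ecrg4(133-148) against Ecrg4(71-132), 40 higher for Fc against PBS, 68 lower for Fc against PBS, 75 higher for Ecrg4(133-148) against PBS, 101 lower for Ecrg4(133-148) against PBS, 163 lower for Ecrg4(71-132) against PBS. Over genes well above background on all 8 arrays, genes over 2-fold in both sets numbered 2 higher for Ecrg4(133-148) against Fc, 0 lower for Ecrg4(133-148) against Fc, 14 lower for Ecrg4(71-132) against Fc, 2 higher for Ecrg4(133-148) against Ecrg4(71-132), 48 lower for Ecrg4(133-148) against Ecrg4(71-132), 3 higher for Fc against PBS, 1 lower for Fc against PBS, 10 higher for Ecrg4(133-148) against PBS, 2 lower for Ecrg4(133-148) against PBS, 31 lower for Ecrg4(71-132) against PBS. With median scaling, genes over 2-fold in both sets numbered 2 lower for Ecrg4(133-148) against Fc, 29 lower for Ecrg4(71-132) against Fc, 40 higher for Ecrg4(133-148) against PBS, 208 higher for Ecrg4(71-132) against PBS, 44 lower for Ecrg4(71-132) against PBS. With quantile normalization, genes over 2-fold in both sets numbered 3 lower for Ecrg4(133-148) against Fc, 33 lower for Ecrg4(71-132) against Fc. With the deposited log2 table, genes over 2-fold in both sets numbered 3 lower for Ecrg4(133-148) against Fc. This paragraph lists only counts that differed from the main count by more than a fixed ratio. Counts not listed for these settings stayed within that ratio of the main count.

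Among 105 named genes and called lists, no sign turned in the settings that keep all arrays. Leaving out 1 array turned the sign of 19, and since that compares means over different sets, these turns may follow from the set difference. With the block as well, 1 of the 24 called lists turned, the NF-kB pathway members and classic targets in Fc against PBS, from -0.141 to 0.963. Without the block the log2 folds ranged as follows. Chemokines in Ecrg4(133-148) against Fc ran from -0.231 to 1.17. Immediate-early genes in Ecrg4(133-148) against Fc ran from -0.0377 to 0.533. Glycolysis and hypoxia response in Ecrg4(133-148) against Fc ran from -0.0887 to 0.489. Interferon-stimulated genes in Ecrg4(71-132) against Fc ran from -0.606 to 2. Interferon-stimulated genes in Ecrg4(133-148) against Ecrg4(71-132) ran from -1.85 to 0.357. Immediate-early genes in Ecrg4(133-148) against Ecrg4(71-132) ran from -0.417 to 0.0965. NF-kB pathway members and classic targets in Fc against PBS ran from -0.0755 to 0.898. Il6 in Ecrg4(133-148) against Fc ran from -0.116 to 3.22. Olr1 in Ecrg4(71-132) against Fc ran from -0.173 to 3.04. Fcgr1 in Ecrg4(71-132) against Fc ran from -2.13 to 0.617. Fcgr2b in Ecrg4(71-132) against Fc ran from -0.194 to 0.493. Fcgr4 in Ecrg4(71-132) against Fc ran from -0.719 to 0.233. Cd36 in Ecrg4(71-132) against Fc ran from -0.704 to 1.1. Cxcl10 in Ecrg4(71-132) against Fc ran from -1.14 to 6.21. Cxcl10 in Ecrg4(133-148) against Ecrg4(71-132) ran from -4.08 to 0.869. Ifit1 in Ecrg4(133-148) against Ecrg4(71-132) ran from -3.06 to 0.37. Rsad2 in Ecrg4(133-148) against Ecrg4(71-132) ran from -2.93 to 0.418. Il6 in Fc against PBS ran from -0.843 to 3.54. Acod1 in Fc against PBS ran from -1.11 to 3.72.

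The slide as a block could not be run, since all arrays were on 1 slide. Signal over background limits the dim genes.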

Other observations

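Some macrophage genes differed between the 2 sets, and those named here were chosen after their values were seen. Cx3cr1, the fractalkine receptor gene of resting microglia, averaged 4.68 (SD 0.06, n = 4 arrays) in set 1 and -1.95 (SD 1.09) in set 2. Fcrls averaged 3.64 and -0.41, and F13a1 1.82 and -3.17. Set 2 was higher in Itgax (5.39 against 0.97), Chil3 (9.17 against 5.29), Mmp12 (5.68 against 1.62), Ccl17 (2.14 against -0.98) and Dcstamp (2.63 against -2.09). Mertk (3.35 against 1.37), Cd33 (3.62 against 1.98) and Selplg (5.14 against 3.87), homeostatic microglia genes like Cx3cr1 and Fcrls, were also higher in set 2. Csf1r (8.08 and 8.07), Trem2 (7.1 and 7.46) and Siglech (6.68 and 7.18) were close. The 21 homeostatic microglia genes as a list had a median difference of 0.117, with 7 over 2-fold higher in set 1 and 4 in set 2. Of the other fixed lists, interferon-stimulated genes had a median difference of 1.82 and cell cycle genes of 1.6, both higher in set 1.

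One hypothesis is that the set 2 cultures were exposed to GM-CSF, a growth factor for macrophages. The test was written before the values of its 12 genes were examined, though after other genes high in set 2 had been seen. Of 10 genes measured, 9 were higher in set 2, with a median of 1.487, at percentile 100 of 10000 random lists of matched level. This is consistent with GM-CSF, but genes that move together make such a percentile extreme more easily, and other signals that act on the same genes were not tested.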
